A study of Mus musculus with 24 samples.

How the data were processed

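RNA was measured by sequencing in kidneys of C57BL/6 mice, wild type or knocked out for Nlrp3 (spelled NLPR3 in the labels). Mice received glyoxylate (Gly) at 75 mg/kg per day or saline, in 200 µl injected into the peritoneum on each day from day 1 to day 7, and kidneys were taken on day 7, per the labels. Glyoxylate is a precursor of oxalate, and the model gives calcium oxalate deposits in the kidney. There were 6 libraries in each of 4 groups, 24 in all. The sample titles gave the group and the replicate number. Libraries were made with the TruSeq RNA kit from 1 µg of total RNA extracted with Trizol, per the labels' protocols. The labels name separate samples, and p-values measure the spread between these samples.

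The values are FPKM (fragments scaled by transcript length and by mapped fragments), computed and deposited by the authors in 1 table with a column per library. Per the submitters' processing notes, Bowtie 0.12.2 and the genome builds mm8 and mm9 were named, with no role given. The program that made the FPKM values, the annotation and the use of strand are not given in the sources used here. The table holds 28450 features, of which 22036 carry an Ensembl mouse gene ID and 6414 are gene models added by the authors. Of the 22036 IDs, 22022 were found in a symbol table and 21995 had the same symbol there. Some genes are not reported here. Gene names were taken from the table itself, and no coordinates are given because the builds named differ from the reference at hand. Transcript lengths, used only in a check of length trends, were the longest transcript per gene in the GENCODE mouse annotation, which gave a length to 94.7% of the tested features.

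FPKM values do not hold read counts. The low values were examined for steps of whole reads: among features averaging under 0.05 FPKM, at most 2.39% shared 1 ratio between 2 libraries, in bins of 0.01 on the log2 scale, so no reads were recovered and the sequencing depth is unknown. No interval that needs a depth is given. The sum of FPKM, from 439749 to 539018 per library, is not a depth.

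The main test was limma 3.58.1 with an intensity trend in R 4.3.3 on log2(FPKM + 1). All 24 libraries entered 1 fit with a mean per group and a shared spread. Features with at least 1 FPKM in at least 6 libraries were tested, 13020 in all, 686 of them added models. Calls have a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes on this scale understate the change of features expressed at low levels. The 5 contrasts were Gly against saline in wild type, Gly against saline in knockout, knockout against wild type under saline, knockout against wild type under Gly, and the interaction, which is the difference between the responses of the genotypes. Single measures per library, and Nlrp3, were compared by exact permutation tests of 6 against 6 libraries, two-sided, with 32 tests in the family. The smallest p such a test can give is 0.0022.

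Before the data were examined, 39 gene lists were fixed for injury, inflammation, nephron segments, other cell types a kidney sample could hold, metabolism, handling and animal sex. They were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Fry asks whether a list moves one way and does not compare it with other genes. Lists with under 3 tested members have values only. Those for T and NK cells and for the adrenal gland had no member past the filter. Genes named in the text follow a rule fixed at the same time: for each of the first 4 contrasts the 10 largest rises and 10 largest falls among called genes averaging at least 5 FPKM in the higher group, without predicted genes, up to 4 members with the smallest p of each list described, the 10 smallest p of the interaction, and Nlrp3. Y-linked genes were in the sex chromosome list. FPKM of families with near identical members, such as the hemoglobin genes, Ugt1a, Serpina1, Gsta and Cyp2d, can be split among members and are uncertain for any 1 member. Antisense and overlapping genes are uncertain for the same reason.

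The test was tried on simulated data built on the real features, with 50 features changed by each of several known sizes. The changed features were drawn only from those above an expression floor that tested features did not have to pass. Noise was independent between features, with the same spread in all groups. The values below hold for that setting, and not for weakly expressed or correlated features or for groups with outlying libraries. In the wild-type Gly contrast, 78% of changes of 0.5 log2 units and 100% of changes of 1 were called, with 3 of 12820 unchanged features called. In the contrast of knockout and wild type under Gly, 78% of changes of -0.5 and 98% of changes of -1 were called, with 10 false calls. For the interaction, these were 44% and 92%, with 12 false calls.

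No 2 libraries held identical values, and the correlation of log2 values across features lay, over all pairs of libraries, between 0.866 and 0.993. The alternatives were other pseudocounts and filters, median-ratio scaling, quantile normalization, array weights, robust variance, fits of only the groups compared, a block for the replicate number, leaving out each library in turn, and a size threshold. Alternatives chosen after seeing the data were leaving out 5 saline knockout libraries without Y-linked transcripts, leaving out wild-type Gly libraries 1 and 5, wild-type saline as the reference for Gly knockout, removal of each library's trend on transcript length, and Ensembl genes only. Python 3.11.15 with matplotlib 3.10.9 drew the plots.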

Results

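Kidney RNA was profiled in 24 libraries, 6 from each of 4 groups: wild-type and Nlrp3 knockout mice, each given saline or glyoxylate (Gly, 75 mg/kg per day for 7 days), a precursor of oxalate that gives calcium oxalate deposits in the kidney. The values were FPKM as deposited by the authors, which sum to between 439749 and 539018 per library. The sequencing depth behind them is unknown. On the log2(FPKM + 1) scale, the first principal component held 52.7% of the variance and parted Gly from saline libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at or near 0 in saline knockout libraries 1, 2, 3, 5 and 6, with no value above 0.0503 FPKM. Saline knockout library 4 and the other 18 libraries expressed them, with Ddx3y between 5.14 and 12.9 FPKM. The labels give no sex. The mean differences within wild type and within Gly therefore came from libraries that all expressed Y-linked genes, and those that include saline knockout did not. The spread in the main test was shared by all 24 libraries, saline knockout included.

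**Figure D1:**
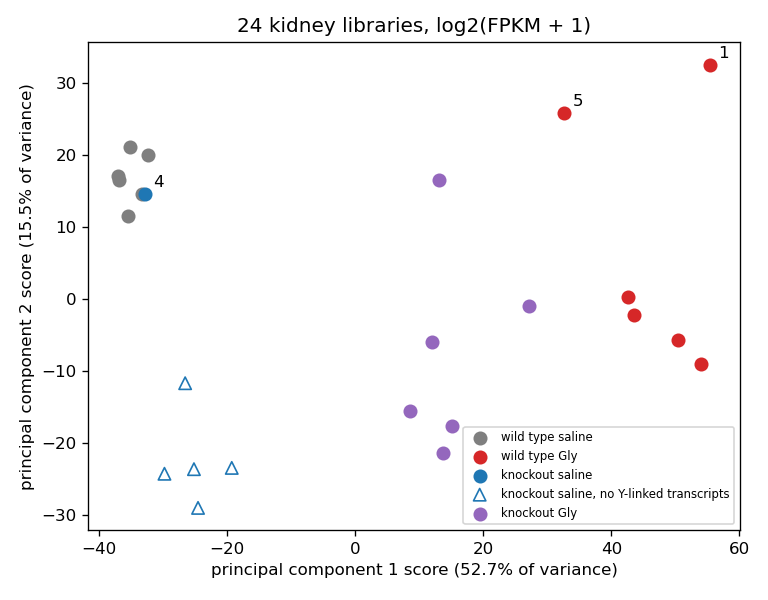
First and second principal component scores of the 24 libraries on log2(FPKM + 1), 1 point per library, coloured by group. Open triangles are the 5 saline knockout libraries without Y-linked transcripts, saline knockout library 4 lies among the saline wild-type libraries, and wild-type Gly libraries 1 and 5 (numbered) lie apart from the other 4 of their group.

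The targeted gene was examined first. Nlrp3 (ENSMUSG00000032691), the sensor protein of an inflammasome, averaged 0.572 ± 0.224 FPKM (SD, n = 6) in Gly wild type and 0.129 ± 0.00910 (SD, n = 6) in Gly knockout. The Gly knockout value was 0.225 of the wild-type value and lower in all 6 libraries than in any Gly wild-type library (exact permutation p = 0.0022, adjusted p = 0.0087 over 32 tests). Under saline, Nlrp3 was at 0.0663 ± 0.0168 FPKM in wild type and 0.0961 ± 0.0626 in knockout (SD, n = 6 each), a difference within the spread (exact permutation p = 0.30). Levels under saline are too low to check the knockout labels. The lower value under Gly does not check them by itself. Genes that were not targeted, such as Ccl2 and Csf1, were lower in Gly knockout by a similar factor, as given below. Gly raised Nlrp3 8.62-fold in wild type (exact permutation p = 0.0022), while in knockout the change was not larger than the spread (exact permutation p = 0.26). Nlrp3 lay below the filter of the main test. With no filter, limma gave a log2 difference between genotypes under Gly of -0.47 ± 0.06 (SE, adjusted p = 2.64e-05) and under saline of 0.04 ± 0.06 (SE, adjusted p = 0.84).

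**Figure D2:**
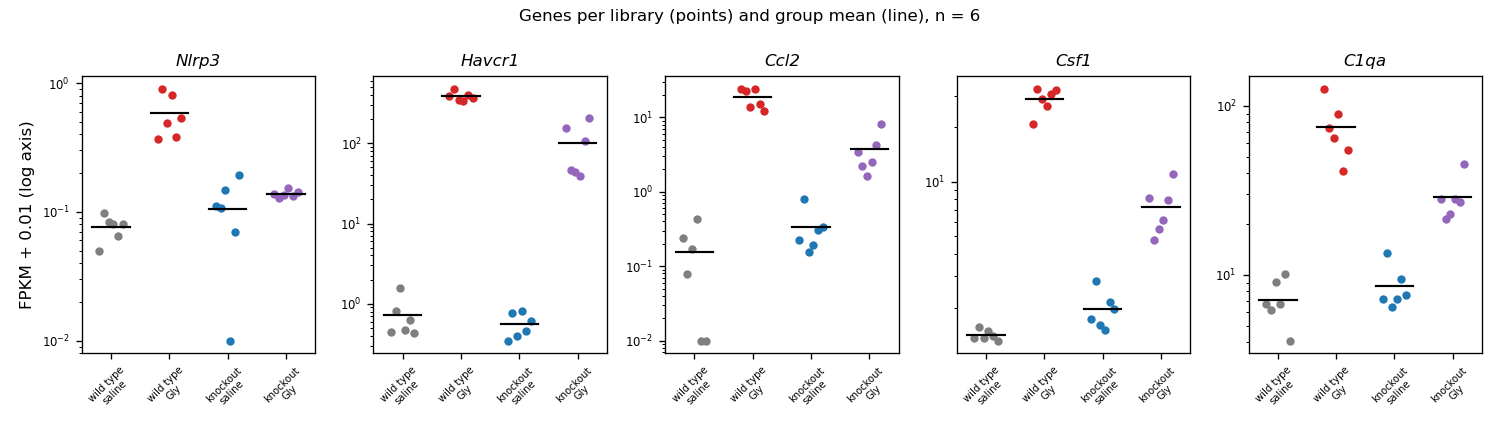
FPKM plus 0.01 on a log axis for 5 genes, 1 point per library, with a line at the mean of each group (n = 6). Havcr1 averaged 386 FPKM in Gly wild type and 100.2 in Gly knockout.

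The first comparison asked how wild-type kidneys changed under Gly. Havcr1, which encodes the tubule injury marker KIM-1, rose from 0.713 ± 0.437 to 386 ± 52.3 FPKM (SD, n = 6; log2 change 7.84 ± 0.29 SE, adjusted p = 1.26e-15). Lcn2, the injury marker NGAL, rose by 5.44 log2 units, Spp1 (osteopontin) by 4.30, Timp1 by 4.601, Vcam1 by 4.12 and the chemokine gene Ccl2 by 4.06. The complement gene C3 rose by 4.50 and the macrophage lysozyme gene Lyz2 by 4.43. Collagen genes Col3a1 and Col1a1 rose by 4.995 and 4.09. Among the largest falls were the organic anion transporter gene Slc22a7 (-3.62), Egf (-3.46), the tyrosine catabolism gene Hpd (-3.44), the gluconeogenesis genes G6pc (-3.19) and Pck1 (-3.12), and Akr1c14 (-3.13). Hemoglobin genes fell as well, with Hbb-bt at -3.09, Hba-a2 at -3.06 and Hbb-bs at -2.93. These copies are near identical and share reads.

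Gene lists fixed before the data were examined described the same libraries by pathway and cell type. All 22 kidney injury genes rose, with a median log2 change of 2.78, and so did all 22 when adjusted over the list alone. All 21 tested genes of NF-kB cytokines and chemokines rose (median 2.16), those with the smallest p being Csf1 (3.61), Cxcl2 (2.49), Ccl12 (2.75) and Cxcl1 (3.86). Of macrophage and monocyte genes 23 of 23 rose (median 2.39, examples C1qc 3.33 and Cd68 2.63), of MHC class II genes 7 of 7 (median 2.29), of interferon response genes 22 of 24 (median 1.41), of fibrosis and matrix genes 25 of 25 (median 2.20) and of cell cycle genes 27 of 27 (median 1.71). Of unfolded protein response genes, 15 of 17 rose (median 1.22). The counts adjusted over the list alone were 21, 23, 7, 22, 25, 27 and 15. Camera called each of these at the preset correlation. With an estimated correlation none of these rising lists was called: adjusted p = 0.099 for injury and for NF-kB genes, 0.27 for macrophage, fibrosis, cell cycle and unfolded protein response genes, 0.30 for MHC class II and 0.33 for interferon genes. Proximal tubule genes fell in 21 of 25 (median -1.02, examples Pck1 -3.12, Fbp1 -1.29 and Slc13a3 -0.91) and fatty acid oxidation genes in 21 of 23 (median -1.02, examples Cpt2 -1.51 and Ehhadh -2.82), the same counts over the list alone. Both of these were also called with an estimated correlation, adjusted p = 0.029 each. Among oxalate and glyoxylate handling genes 9 of 15 fell and 2 rose (median -0.36, examples Gcdh -0.97 and Hoga1 -0.77), with the same counts over the list alone and adjusted p = 0.099 with an estimated correlation. Of the inflammasome and IL-1 list 10 of 15 rose and 3 fell (median 0.80, 11 and 3 over the list alone), and camera did not call it (adjusted p = 0.32). Listed genes below the filter, among them Casp1, Il1a and Aim2, were not tested.

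In all, 8265 of 13020 features changed under Gly in wild type, 6537 higher and 1728 lower, and 1659 by at least 1 log2 unit. The median of all features rose by 0.26 on the log2 scale. After median-ratio scaling the median was -0.00 and 7456 features were called, 3771 higher and 3685 lower. The list directions above held under that scaling, with 22 of 23 macrophage genes called higher and 25 of 25 proximal tubule genes lower. Quantile normalization gave 3674 higher and 4103 lower. The share of FPKM in mitochondrial transcripts was 29.6% ± 2.84 under saline and 19.5% ± 3.44 under Gly (SD, n = 6, exact permutation p = 0.0022, adjusted p = 0.0087), and that in ribosomal protein transcripts was 2.56% ± 0.152 and 5.76% ± 1.62 (SD, n = 6, exact permutation p = 0.0022, adjusted p = 0.0087). Wild-type Gly libraries 1 and 5 stood apart, with ribosomal shares of 8.97% and 5.82% against at most 5.07% in the other 4 of the group.

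The next comparison asked how Gly knockout differed from Gly wild type. Havcr1 averaged 100.2 ± 70.1 FPKM against 386 ± 52.3 (SD, n = 6; log2 difference -2.23 ± 0.29 SE, adjusted p = 1.12e-05). Ccl2 was lower by 2.15 log2 units (3.69 ± 2.40 against 18.6 ± 5.42 FPKM, SD, n = 6), Csf1, the growth factor for macrophages, by 1.88 (7.24 ± 2.303 against 28.6 ± 4.45), Atf3 by 1.62, Tnfrsf12a by 1.61 and Timp1 by 1.52. Defb36, Ubd, Aoc1 and Cyp2a4 were also among the largest falls, at -2.05, -1.66, -1.48 and -1.77. Among the genes higher in the knockout were Hpd by 2.78, G6pc by 2.05, Egf by 1.92, Igfbp1 by 2.40, Upp2 by 1.82, and Cyp4a14 and Cyp4a10 by 2.12 and 1.81. Ugt1a2 (2.86 higher) and Cyp2d26 (1.98 higher) belong to families that share sequence. Ugt1a2 also varied widely in Gly knockout, at 135 ± 136 FPKM (SD, n = 6).

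By list, 16 of 22 kidney injury genes were lower in Gly knockout and 1 was higher (median -0.71). Of NF-kB cytokines and chemokines 18 of 21 were lower (median -0.88, examples Cxcl2 -1.46 and Ccl12 -1.48), of macrophage and monocyte genes 22 of 23 (median -0.95, examples Fcer1g -1.39 and C1qc -1.28), of MHC class II genes 7 of 7 (median -1.20), of interferon response genes 18 of 24 (median -0.58, example Cxcl10 -1.14), of fibrosis and matrix genes 15 of 25 (median -0.56, example Tgfb1 -0.83) and of unfolded protein response genes 13 of 17 (median -0.73, example Atf4 -0.84). Heat shock genes, a list fixed to stand for handling, were lower in 9 of 10 (median -0.69, example Dnajb1 -1.01). Adjusted over the list alone, 18, 20, 22, 7, 19, 18, 14 and 9 were lower. Of cell cycle genes 20 of 27 were lower (median -0.50), and 13 after median-ratio scaling. In the inflammasome and IL-1 list, which leaves out Nlrp3, 8 of 15 were lower (Gsdmd -0.79, Pycard -0.57, Il18 -0.45) and 1 was higher (Nlrp6, 0.91), and camera did not call the list (adjusted p = 0.22). Casp1 lay below the filter, so this result does not cover it. Fatty acid oxidation genes were higher in 20 of 23 (median 0.65, example Ehhadh 1.503), proximal tubule genes in 17 of 25 (median 0.60, examples Pck1 1.78, Slc6a19 1.51) and oxalate and glyoxylate handling genes in 8 of 15, with 1 lower (median 0.34, examples Gcdh 0.60, Aldh4a1 0.84). Over the list alone these were 23, 20 and 9. Camera called all of these lists except the inflammasome list at the preset correlation, and none with an estimated one: adjusted p = 0.058 for fatty acid oxidation and proximal tubule, 0.070 for NF-kB genes, 0.125 for oxalate handling, 0.145 for heat shock, 0.21 for the unfolded protein response, 0.27 for injury, macrophage and MHC class II genes, 0.39 for interferon and cell cycle genes and 0.42 for fibrosis.

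**Figure D3:**
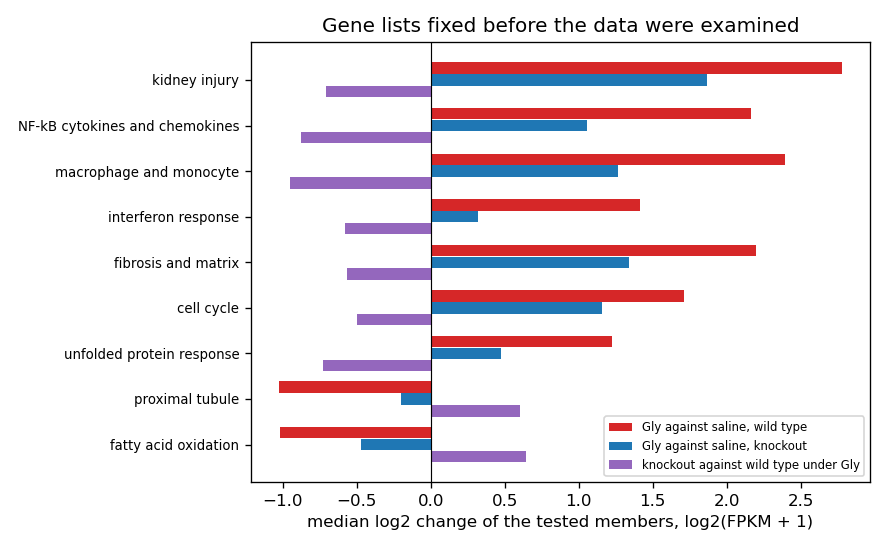
Median log2 change of the tested members of 9 gene lists in 3 contrasts, as bars from 0. The kidney injury list moved by 2.78 with Gly in wild type and by 1.86 with Gly in knockout, and was lower by 0.71 units (median -0.71) in Gly knockout than in Gly wild type.

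In all, 3882 features differed between Gly knockout and Gly wild type, 1090 higher and 2792 lower in knockout, and 196 by at least 1 log2 unit. Median-ratio scaling gave 1693 higher and 2001 lower, and quantile normalization 2032 higher and 2236 lower. With only the 12 Gly libraries in the fit the count was 2168. The mitochondrial share was 23.9% ± 1.10 in Gly knockout against 19.5% ± 3.44 in Gly wild type (SD, n = 6, exact permutation p = 0.0065, adjusted p = 0.0173), and the ribosomal share 4.09% ± 0.444 against 5.76% ± 1.62 (SD, n = 6, exact permutation p = 0.0022, adjusted p = 0.0087). Wild-type Gly library 1 lay apart at 8.97%, and without it, chosen after its value was seen, the wild-type mean was 5.11% ± 0.405 (SD, n = 5, exact permutation p = 0.0043).

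Knockout kidneys also responded to Gly. Relative to saline knockout, Havcr1 rose by 5.73 log2 units, Lcn2 by 5.14, Col3a1 by 3.82, C3 by 3.64, the fibrinogen gene Fgg by 3.85 and Lyz2 by 3.14, while Slc22a7 fell by 3.94 and Pvalb, a marker of the distal convoluted tubule, by 3.02. Sec14l3 and C8a fell by 2.59 and 2.45, and the hemoglobin genes Hbb-bt, Hbb-bs, Hba-a2 and Hba-a1 by 2.86, 2.77, 2.74 and 2.68. All 22 injury genes rose (median 1.86), as did 20 of 21 NF-kB genes (median 1.06), 21 of 23 macrophage genes (median 1.27), 25 of 25 fibrosis genes (median 1.34) and 26 of 27 cell cycle genes (median 1.16), and 16 of 23 fatty acid oxidation genes fell (median -0.47). Adjusted over the list alone, these were 22, 21, 21, 25, 26 and 17. With an estimated correlation the adjusted p = 0.034 for injury, 0.049 for NF-kB and fatty acid oxidation, 0.13 for fibrosis and cell cycle and 0.14 for macrophage genes. Without the 5 libraries lacking Y-linked transcripts, which leaves 1 saline knockout library, the spread of that group comes from the others and the counts were 18 for injury (median 1.996), 14 for NF-kB (1.23), 13 for macrophage (1.35), 17 for fibrosis (1.33), 1 for cell cycle (0.83) and 2 for fatty acid oxidation genes (-0.36). Interferon response genes rose in 8 of 24 and fell in 1 (median 0.32, 8 and 1 over the list alone), and in 3 after median-ratio scaling. Of the inflammasome and IL-1 list 6 of 15 rose (median 0.23, 6 over the list alone). Camera called neither list (adjusted p = 0.27 and 0.13, and 0.75 and 0.49 with an estimated correlation). At the preset correlation it called the inflammasome list after median-ratio scaling (adjusted p = 0.025) and the interferon list without the 5 libraries, on 1 saline knockout library (median 0.67, adjusted p = 0.00076). Compared with saline wild type, 19 of 24 interferon genes were higher in Gly knockout, 20 over the list alone (median 0.81, camera adjusted p = 0.00024, and 0.48 with an estimated correlation). Other large changes were in genes that also differed, in the opposite direction, between saline knockout and saline wild type: Eif2s3y (3.69), Slc7a13 (4.07), Acsm3 (3.31) and Serpina1a (3.26) rose, and Akr1c18 (-3.75) and Aadat (-2.43) fell. Without the 5 libraries, Slc7a13 was at -1.73 (adjusted p = 0.16) and Acsm3 at -2.27 (adjusted p = 0.10).

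Gly changed 3837 features in knockout, 3092 higher and 745 lower, or 1608 and 1549 after median-ratio scaling and 1699 and 1892 after quantile normalization. The median of all features rose by 0.12. Without the 5 libraries the count was 741, resting on 1 saline knockout library. Gly knockout differed from saline wild type, where every library expressed Y-linked genes, in 5943 features, 5068 higher and 875 lower, with all 22 injury genes higher (median 2.10). Array weights gave 6058 calls for the response in knockout. Across features, which are not independent replicates, the log2 changes under Gly in the 2 genotypes correlated with Pearson r = 0.71 and Spearman rho = 0.71, and r = 0.82 without the 5 libraries. Features higher in both numbered 2835, where independent lists would share 1552, and those lower in both 559, where independent lists would share 98.9. Another 52 changed in opposite directions.

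**Figure D4:**
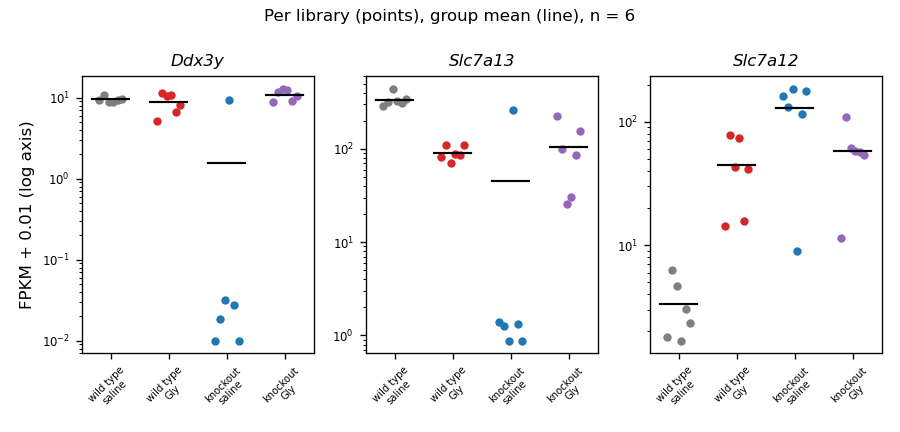
FPKM plus 0.01 on a log axis for the Y-linked gene Ddx3y and the sex-biased genes Slc7a13 and Slc7a12, 1 point per library, with a line at the group mean (n = 6). In saline knockout, 1 library lies with the saline wild type in Ddx3y and Slc7a13 and the other 5 lie far below.

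The largest differences between saline knockout and saline wild type included genes with known sex bias in mouse kidney. The female-biased genes rose in 7 of 7 (median 2.43, examples Slc7a12 4.597, Slc22a29 2.71 and Prlr 2.90) and the male-biased genes fell in 6 of 9, with 1 higher (median -4.62, examples Slc7a13 -6.14, Acsm3 -5.97 and Cyp7b1 -4.62). All 4 Y-linked genes fell. Over the list alone the counts were 7, 7 and 4. With an estimated correlation adjusted p = 0.072 for each of the sex-biased lists and 0.050 for the Y-linked genes. The same sex-biased lists hold Akr1c18 (2.43, female-biased), Slco1a1 (-5.16) and Cyp2j13 (-4.76, both male-biased). Outside these lists, Ugt1a2 (6.54), Ugt1a1 (3.10), Abcc3 (3.16), Cbr1 (2.84), Gsta1 (2.26) and Rdh16f2 (2.21) were higher. Cyp4a12a (-4.18), Pzp (-3.35), Ugt2b37 (-3.34) and Azgp1 (-3.27) were lower. For these lower genes, saline knockout library 4, which expresses Y-linked genes, lay far above the other 5. It was at 42.2, 30.3, 51.6 and 59.8 FPKM, against at most 1.96, 0.836, 0.934 and 5.78. Endothelial genes were higher in 7 of 13 (median 0.50, adjusted p = 0.53 with an estimated correlation) and podocyte genes in 5 of 8 (median 0.55, adjusted p = 0.53). Adjusted over the list alone, these were 11 and 7. No gene of either list was called without the 5 libraries lacking Y-linked transcripts (medians 0.0843 and 0.145). No macrophage or NF-kB gene was called. Of interferon response genes 4 of 24 were higher, or 15 over the list alone (median 0.42, camera adjusted p = 1.65e-05, and 0.81 with an estimated correlation), and none without those 5 libraries (median 0.16).

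The count for this comparison was 1379, with 901 higher and 478 lower, or 645 and 743 after median-ratio scaling and 643 and 696 after quantile normalization. Without the 5 libraries lacking Y-linked transcripts limma called 0 features (1 saline knockout library left, 101 of 13020 at an unadjusted p under 0.05). Leaving out single libraries moved the count by over 1.5 times for saline knockout libraries 1 (817), 2 (843), 6 (832) and 4 (2116). Array weights gave 5560, only the groups compared 2746, and the fit without wild-type Gly libraries 1 and 5 gave 2660.

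The interaction asked whether the response to Gly differed between the genotypes. Gly raised Csf1 less in knockout than in wild type, by 2.16 log2 units (SE 0.20, adjusted p = 8.21e-07), and likewise Hspb1 by 2.35 units (-2.35), Aldh1a2 (-2.24), Ier5 (-1.60), Klrg2 (-1.56), Pdgfb (-1.46) and Cxcl2 (-1.45). The acyl-CoA thioesterase gene Acot12 (1.67) and Cmbl (1.49) had positive interactions. For both, saline knockout library 4, which expresses Y-linked genes, lay above the other 5. It was at 63.1 FPKM against at most 43.1 for Acot12, and at 142 against at most 96.8 for Cmbl. Both interactions therefore rest in part on the 5 libraries that lack Y-linked transcripts. The other interactions named here use the same 5 libraries, and how far they rest on them is not given. For Csf1, saline knockout library 4 was at 1.51 FPKM and the other 5 between 1.59 and 2.80. Of macrophage genes 21 of 23 had a negative interaction (median -1.20), of interferon genes 20 of 24 (median -1.06), of NF-kB genes 18 of 21 (median -0.99) and of injury genes 15 of 22 (median -1.08), while 16 of 25 proximal tubule genes had a positive one (median 0.73). Over the list alone these were 22, 22, 21, 16 and 17. With an estimated correlation adjusted p = 0.040 for the proximal tubule, 0.0998 for NF-kB and 0.29 for the other lists. With 1 saline knockout library left, after leaving out the 5 that lack Y-linked transcripts, the called members were 0 for macrophage (median -1.05), 1 for interferon (-0.78), 3 for NF-kB (-0.87), 0 for injury (-0.83) and 0 for proximal tubule genes (0.53). The inflammasome and IL-1 list had 4 of 15 negative and 1 positive (5 and 1 over the list alone), and camera did not call it (adjusted p = 0.73).

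The interaction was called in 3457 features, 818 positive and 2639 negative, or 1398 and 1425 after median-ratio scaling and 1459 and 1638 after quantile normalization. The median over all features was -0.16. Without the 5 libraries it was called in 10 features, 1 positive and 9 negative, and array weights gave 6896. Without wild-type Gly libraries 1 and 5 the count was 5719.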

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

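The tests on animal sex and the one on whether transcript length was the whole cause were chosen only after the results were seen, and the other tests of explanations here were written before their results.

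In each group of 6 libraries, a library far from the others by Dixon's test at the 95% level was looked for in 6 library measures and 68 named genes. Of 296 groups tested, 53 had such a library, where chance gives about 5% of groups. Saline knockout library 4 lay above its group for Ddx3y at 9.33 FPKM, Eif2s3y 16.2, Slc7a13 263, Acsm3 243, Cyp7b1 105, Cyp2j13 54.5, Cyp4a12a 42.2, Slco1a1 54.4, Pzp 30.3, Ugt2b37 51.6, Azgp1 59.8, Serpina1a 40.3, Cyp2a4 296, Akr1c14 91.6, Cmbl 142 and Acot12 63.1, and below it for Aadat at 119 FPKM, Rdh16f2 53.6 and Spp1 461. Saline knockout library 2 was highest for the hemoglobin share at 0.825%, for Hba-a1 at 1159 FPKM, Hba-a2 1090.2, Hbb-bs 1277 and Hbb-bt 560.1, and for Ccl2 at 0.790. Gly knockout library 1 was highest for Azgp1 at 59.3 FPKM, Cyp2a4 172.7, Cyp4a12a 59.3, Pzp 12.4 and Defb36 1.76.

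Wild-type Gly library 1 was highest for the FPKM total of 539018, the ribosomal share of 8.97%, Lcn2 at 276 FPKM, Timp1 39.95, Ubd 27.3 and Defb36 15.7. Wild-type Gly library 5 was highest for the hemoglobin share at 0.13%, Hba-a1 at 167 FPKM, Hba-a2 168, Hbb-bs 184, Hbb-bt 75.6, Fgg 103 and Gsta1 20.1, and lowest for G6pc at 16.4 and Igfbp1 at 0.771. Saline wild-type library 1 had the highest FPKM total of its group, 529091. Saline wild-type library 3 was highest for Aadat at 203 FPKM, Slc7a13 444, Tnfrsf12a 16.4, Havcr1 1.55, Defb36 0.391 and Cxcl2 0.0506, and library 4 for Klrg2 at 0.710.

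The response to Gly differed between the genotypes by the test of the interaction in 3457 features. Among those with the smallest p, 9 are given here, with log2 interactions of -2.16 for Csf1, -1.60 for Ier5, -1.45 for Cxcl2, -1.56 for Klrg2, -1.46 for Pdgfb, 1.67 for Acot12, -2.35 for Hspb1, -2.24 for Aldh1a2 and 1.49 for Cmbl.

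The first pattern is the difference between saline knockout and saline wild type. For the genes called under saline, the knockout acting alike under both treatments is argued against as the main source of their difference. Over these genes, the median ratio of the difference under Gly to that under saline was -0.0435, with 47.1% of signs shared. They were called with the 5 libraries lacking Y-linked transcripts in the group. The ratio therefore does not speak to a smaller effect of the knockout in them, or to one in other genes. Chance is argued against for the count, since 1 of 100 splits of the 12 saline libraries, the real one, gave 1379 calls or more. The highest other split gave 1. Animal sex is a candidate explanation. Saline knockout library 4, which expresses Y-linked genes, lay at a median 0.168 of the distance of the other 5 from saline wild type. Each of those 5 lay at 0.90 or more of the distance of the rest. The genes were called with these 5 in the group, so their high ratios are largely set by that choice and are no independent reference. The value for library 4 rests on 1 library. The Y-linked genes were at most 0.0503 FPKM in these 5 libraries, which argues against litter alone for those genes. For the other genes, litter or any other property shared by the 5 libraries stays open. An effect of the genotype that appears only under saline stays open for them as well.

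The second pattern is the lower expression of macrophage and kidney injury genes in Gly knockout, with the interaction that goes with it. Argued against are animal sex for the Gly libraries, of which 0 of 12 had Ddx3y under 1 FPKM, and the authors' scaling and the wild-type Gly libraries that stand apart, since 38 of 45 tested genes of both lists stayed lower after median-ratio scaling and 38 of 45 without those libraries. For the counts of all called features, chance is argued against. Of 100 splits 1, the real one, gave as many calls as the 3882 observed, the highest other 2812. For the interaction 1 of 100 regroupings, the real one, gave as many as 3457, the highest other 282. The genes of both lists were not regrouped by themselves, so chance was not tested for them. For the interaction, sex cannot be told apart, in part or as the whole cause: the median ratio of 0.737 between interactions without and with the 5 libraries rests on 1 library, and that of 0.672 between the genotype difference under Gly and the interaction shares the Gly libraries, where shared noise alone would give 0.5, and a genotype effect masked by sex under saline would raise it as well. A smaller response to Gly in the knockout stays open as a hypothesis. Crystal load, batch, handling and time of injury, which were not measured here, stay open as well. Heat shock genes, a list fixed to stand for handling, were also lower in Gly knockout.

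The third pattern is the distance of wild-type Gly libraries 1 and 5 from the other 4 libraries of their group. A part played by transcript length cannot be told apart: the rank correlation of the deviation from the group mean with length was -0.69 for library 1 and -0.35 for library 5, against up to 0.62 in their group, where centring moves the other 4 the opposite way, and 0.57 in size in the other groups. The bound written before, that a library inside this range excludes length, was met by library 5 but was wrong, since a trend elsewhere does not forbid one here. Removal of the trend on length brought the distance of library 1 from 0.618 to 0.450 and that of library 5 from 0.474 to 0.322, still above the 0.217 of the farthest of the other 4, which argues against length as the whole cause and not against a part. RNA quality and differences in injury stay open as untested, and no biological explanation was tested.

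For the remaining counts, 1 of 100 splits of the 12 wild-type libraries gave as many calls as the 8265 under Gly, with 4811 as the highest other. Of the knockout libraries, 1 of 100 splits gave as many as 3837, with 839 as the highest other. Chance is argued against for both counts, where the 1 of 100 was the real split.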

How the results depend on the processing

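The settings that leave out the 5 saline knockout libraries or wild-type Gly libraries 1 and 5, use saline wild type as the reference, remove the length trend or keep Ensembl genes only were chosen after seeing the data. Without single libraries the count of called features ranged from 7892 to 8687 for Gly in wild type, 3080 to 3708 for Gly in knockout, 817 to 2116 for the genotypes under saline, 3213 to 4263 under Gly and 2918 to 4279 for the interaction. Replicate numbers did not pair the libraries (1, 0, 1 and 3 of 6 pairs above 0.1 in the first 4 contrasts); with the replicate number as a block the 5 counts were 8217, 3698, 1165, 3707 and 3266, all within 1.5 times.

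For Gly in wild type, a mean of at least 5 FPKM left 5403 calls, from fewer features tested, and a log2 change of at least 1 left 1659. For Gly in knockout the size threshold left 437, array weights gave 6058, saline wild type as the reference 5943, and leaving out the 5 libraries 741. For the genotypes under saline, a mean of at least 5 FPKM left 916, the size threshold 210, leaving out the 5 libraries 0 in limma (101 at an unadjusted p under 0.05), array weights gave 5560, only the groups compared 2746 and leaving out wild-type Gly libraries 1 and 5 gave 2660. Under Gly the fit of only the groups compared gave 2168 and the size threshold 196. For the interaction, array weights gave 6896, leaving out wild-type Gly libraries 1 and 5 gave 5719, the size threshold 548 and leaving out the 5 libraries 10. There the genes called with all libraries had a median size of 0.613 with a median SE of 0.163, against 0.422 and 0.248 without the 5, from fewer samples. The correlation of the responses moved from 0.71 to 0.82 without the 5. Otherwise the cause was not tested.

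Without the 5 libraries, these turned direction, which for lists is that of camera relative to all genes. For Gly in knockout: medians of collecting duct 0.32, endothelial 0.31 and female-biased genes 1.15, and Slc7a13 -1.73, Acsm3 -2.27, Foxi1 0.0911, Emcn 0.0756, Slc26a1 -0.0531 and Slc22a29 1.15. For the genotypes under saline: proximal tubule 0.0751 (its median kept its sign), thick ascending limb -0.11, collecting duct -0.0680, oxalate handling 0.0677 and sex chromosome genes 0.00758, and Ugt1a1 -0.32, Akr1c18 -0.54, Cyp7b1 0.14, Eif2s3y 0.0263, Pzp 0.33, Ugt2b37 0.89, Acsm2 0.0875, Ptger3 -0.0110, Cldn19 -0.10, Dao 0.0322 and Uty 0.13. For the interaction: Cyp4b1 -0.0896, Cyp7b1 -1.0005, Eif2s3y -0.18 and Uty -0.10. With saline wild type as the reference, Slc7a13 was -2.07, Acsm3 -2.66, Nphs1 0.11, Emcn 0.34 and Slc22a29 1.48. With the length trend removed, Atp6v1g3 in wild type was -0.0117. List medians that turned sign while camera kept its direction were, without the 5 libraries, podocyte (-0.20 to 0.26) and clock genes (0.0562 to -0.30) for Gly in knockout, liver genes (-0.17 to 0.0585) under saline, and male-biased (3.15 to -0.0896) and oxidative stress genes (0.0745 to -0.0456) for the interaction. In other settings they were collecting duct genes for Gly in wild type, clock genes for Gly in both genotypes and oxalate handling genes for Gly in knockout. The cause was not tested for these. Over 428 gene and 108 list results, 270 and 210 gene and list values in all settings kept their direction and lost their call.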

Other observations

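Genes of the stone matrix were among those that rose under Gly in wild type: Spp1 (4.30), Mgp, the matrix Gla protein that inhibits calcification (3.80), Anxa2 (2.19) and Bgn (2.53). Of this list of 20 genes, 9 rose and 3 fell, and camera did not call it (adjusted p = 0.67, and 0.81 with an estimated correlation). In Gly knockout compared with Gly wild type, Mgp was at -1.41, Anxa2 at -0.66 and Spp1 at -0.76, and the dicarboxylate and citrate transporter gene Slc13a2 at 0.96. Of the list, 4 were lower and 3 higher. Adjusted over the list alone, the counts were 9 and 3 in the first comparison and 4 and 3 in the second.

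Male-biased genes fell under Gly in wild type in 8 of 9 tested (median -2.04, 8 over the list alone), with Slc22a7 at -3.62, Kap at -2.04 and Cyp4b1 at -1.42 (adjusted p = 0.27 with an estimated correlation). Kap and Slc7a13 are also in the proximal tubule list, which fell in 21 of 25. Slc22a7 fell under Gly in knockout as well, where most saline libraries lack Y-linked transcripts. Whether the fall concerns sex bias was not tested. Of 7 tested female-biased genes, 1 rose (Slc7a12, 3.23) and 1 fell (median -0.08, the same counts over the list alone), and camera did not call that list (adjusted p = 0.21). Genes of the distal convoluted tubule fell in 7 of 8, with 1 higher (Pvalb -2.65, Calb1 -1.07, Slc12a3 -0.69, and Trpv5 at 0.81, the same counts over the list alone, adjusted p = 0.27 with an estimated correlation). Cholesterol synthesis genes Fdps (1.71) and Sqle (1.74) rose, in a list with 8 higher and 2 lower of 16, the same over the list alone, that camera did not call (adjusted p = 0.97, and 0.99 with an estimated correlation). Clock genes moved both ways, with Nr1d1 at 1.36 and Cry1 at -1.05, in a list with 2 higher and 5 lower of 13, the same over the list alone. Camera called it lower (adjusted p = 0.020, and 0.33 with an estimated correlation) although its median was 0.08. Immediate early genes, a list fixed to stand for handling, rose in wild type in 12 of 15 and fell in 1 (median 1.41). Camera called that list higher at the preset correlation (adjusted p = 0.0011) and not with an estimated one (adjusted p = 0.33). Under Gly in knockout, 10 of 15 immediate early genes rose (median 0.86).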
